A study of Rattus norvegicus with 25 samples.

How the data were processed

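Tooth and periodontal ligament of rats were profiled after the maxillary first molar had been taken out, left dry and put back into its socket. Per the labels, drying lasted 5 min in the immediate replantation group (IR) and 60 min in the delayed replantation group (DR), and tissue was taken 3 or 7 days later. Each of the 4 replanted groups held 6 libraries, and 1 library came from a sample labelled NT, with control given as both its treatment and its time. All libraries carry the same age, postnatal day 21, and the labels do not say whether it is the age at replantation or at collection, so NT can differ in age from the replanted groups. The labels do not say either whether the libraries came from separate animals, so p-values of genes and of values per library measure only the spread between libraries. Replicates are numbered 1 to 6 in the labels, while the deposited names number the day 7 libraries 2 to 7, so a number shared across days pairs different libraries under each numbering.

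Per the labels' protocols, RNA was taken up in Trizol, and 500 ng of total RNA went into each library made with the Lexogen QuantSeq kit, which sequences a short stretch near the 3′ end of each polyadenylated transcript. A count therefore stands for a transcript end and does not grow with transcript length. The deposited values are whole-number read counts per gene symbol, 1 file per library, not normalised. Per the submitters' processing notes, Bowtie2 and edgeR were used with the builds mm10 and rn6. Which build served which step, the versions, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here. Reads shared by near-identical genes, by overlapping neighbours or by antisense partners cannot be told apart without those settings, so values of such genes are uncertain.

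Each file held 17048 entries with 16881 distinct symbols and no blank name. For 149 symbols there was more than 1 entry, 316 entries in all, and 41 of these symbols had identical counts in each of their entries and in all libraries. For each repeated symbol the entry with the highest total over the libraries was kept, a choice made after the files had been read. Of the symbols, 14393 equalled a symbol of the GRCr8 gene table, a further 2096 equalled a synonym in it, and 392 had no match. That table was used for names and for neighbouring genes only, because its build differs from those in the processing notes, and no coordinates are given. No column of any other series was used.

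Depth ran from 5.04 to 8.81 M counts per replanted library and was 8.55 M in NT. Between 11342 and 13277 genes had at least 1 count in a library, and 1668 symbols had 0 counts in all 25 libraries. Entries for ribosomal RNA (Rn45s, Rn18s, Rn28s and Rn5-8s) took 9.74% to 33.8% of the counts in the replanted libraries and 2.91% in NT. QuantSeq reads carried no molecular identifiers in the sources used here, so counting error is a lower bound on the error of a value.

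Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 24 replanted libraries entered 1 quasi-likelihood model with 4 group means (TMM scaling, filterByExpr by group, robust fit, 20 residual degrees of freedom), which left 11492 genes. All groups shared the estimate of spread. The 5 contrasts were DR against IR at day 3, DR against IR at day 7, day 7 against day 3 in IR, day 7 against day 3 in DR, and the interaction, which is the drying effect at day 7 minus that at day 3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 fold changes with their standard error (SE), and levels are log2 CPM (counts scaled to the effective library size) with a prior count of 2, given as mean ± SD over 6 libraries. All adjusted p-values of genes are edgeR's unless another tool is named. NT has no replicate, so its comparison with the replanted groups has no p. It uses log2 ratios of mean CPM with 5 CPM added, and a gene list is placed by the percentile of its median among 10000 random lists matched for size and expression.

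Before the data were examined, 35 lists of cell-type markers and pathway genes were fixed, together with the groups, the contrasts, the tests, the alternatives and the rule for naming genes. Lists with at least 4 tested members, 34 of the 35, were tested with camera (limma 3.58.1, preset correlation of 0.01, two-sided, adjusted over the 34 lists within a contrast). Camera asks whether a list's members rank above or below all other genes. The camera calls were set beside camera with an estimated correlation, fry, and a two-sided exact permutation test of the list mean per library, whose smallest p for 6 against 6 libraries is 0.00216. The count of members past the threshold is also given adjusted over the list alone. Named genes per contrast were the 6 highest and 6 lowest called genes with an average log2 CPM of 3 or more, up to 4 called members of each described list or, with none called, the 2 of smallest p, and 12 genes of resorption, matrix and inflammation whatever their p. Where fewer than 10 genes were called, the 10 of smallest p at that expression were named as well. For 1 gene that this rule names the value is not reported here. Against NT, the rule took the 8 highest and the 8 lowest ratios among genes at 20 CPM or more whose ratio had 1 sign in all 24 libraries.

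Alternatives fixed beforehand were scaling by RLE and by upper quartile, no filter, a stricter filter (5 CPM in 6 libraries), DESeq2 1.42.0, limma-voom, limma-voom with sample quality weights, the replicate number as a block, an adjusted p under 0.01, the compared groups alone, and each library left out in turn. Whether numbers pair the libraries was judged from the data, since no label says so, by the correlation of deviations from the group means. At day 7 all 6 pairs of IR and DR libraries of the same number correlated over 0.1 (0.214 to 0.721), and 5 of 6 were closest to their own number. The mean of 0.335 was the highest of all 720 orders (exact permutation p = 0.00139, 1 of 6 group pairs examined). DR against IR at day 7 is therefore also given with the number as a block in the day 7 libraries, with camera and with an exact sign-flip test of paired list means. After the data had been seen, 4 more lists were written for tissues that lie near the molar, namely a lipid-secreting gland list (sebaceous and Harderian, 12 of 18 members tested), a nasal gland list (12 of 12), an olfactory epithelium list (12 of 17) and a ciliated respiratory epithelium list (12 of 17). Added after seeing the data were also a fit without the 6 libraries in which the lipid gland list took over 2% or the nasal gland list over 20% of the counts, fits with the mean of 1, 3 or 6 tissue lists as covariates, a fit without the ribosomal RNA entries, the exact permutation test of list means, the fit and tests with pairs at day 7, camera with an estimated correlation in the fits with 3 covariates, without the 6 libraries and with pairs, and camera after the other scalings. The 6 covariates were the 4 lists of nearby tissues and the lists of skeletal muscle and of gingival epithelium and keratinocyte. RLE and upper-quartile scaling moved the median log2 fold change of all genes by less than 0.1 in each contrast.

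The steps were tested on simulated counts with the means, dispersions and library sizes of the real data and a seeded set of genes altered by known folds. With no gene altered, edgeR called 0 or 1 of 11334 genes per contrast. Simulated genes vary independently, whereas the real libraries share strong common variation, so the simulation bears on counting depth and dispersion and not on that shared variation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.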

Results

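RNA was measured in the tooth and the periodontal ligament, the fibrous tissue that holds a tooth in its socket, after rat maxillary first molars had been removed, dried and replanted. Drying lasted 5 min in the immediate group (IR) and 60 min in the delayed group (DR), and each was sampled at day 3 and day 7 with 6 libraries per group. NT held 1 library, and 11492 genes were tested over the 24 replanted libraries.

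The libraries of day 3 lay farther from their group means than those of day 7. Taken as the root mean square over genes of the log2 CPM difference to the mean of the other libraries of the group, the distance was 1.16 ± 0.345 at day 3 and 0.776 ± 0.143 at day 7 (SD, n = 12 each, permutation p = 0.00048). The group means were 1.31 in IR day 3, 1 in DR day 3, 0.783 in IR day 7 and 0.769 in DR day 7. The first component of a principal component analysis held 39.5% of the variance and the second 19.7%. Along the first, IR day 3 replicate 6 (-156.9) and DR day 3 replicates 1 to 3 (-101.1, -109.9 and -124.9) stood apart from the day 7 libraries, which ran from -7.434 to 72.98.

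**Figure D1:**
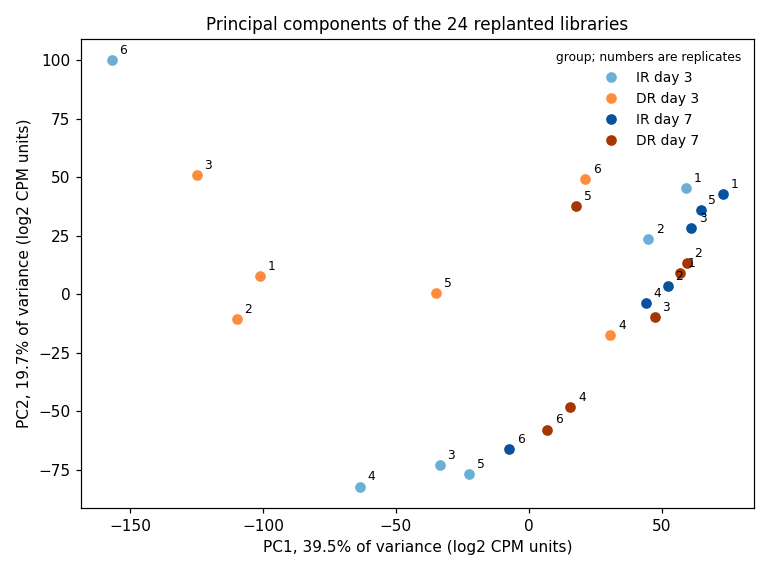
Principal components 1 (x axis, 39.5% of variance) and 2 (y axis, 19.7% of variance) of log2 CPM in the 24 replanted libraries, 1 point per library, coloured by group and numbered by replicate. Day 3 libraries spread from -156.9 to 59.26 on the x axis, and day 7 libraries lie between -7.434 and 72.98.

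Genes of glands and nasal tissue, which lie near the upper molars, took unequal shares of the counts. The lipid-secreting gland list (Elovl3, Mogat1, Thrsp and other lipid genes of sebaceous and Harderian glands) took 1.44% ± 1.2 of counts in DR day 3, 0.63% ± 1.48 in IR day 3, 0.147% ± 0.256 in DR day 7 and 0.0464% ± 0.0198 in IR day 7 (SD, n = 6). In DR day 3 the first 3 replicates held 2.22%, 2.16% and 3.04%, and in IR day 3 replicate 6 alone held 3.65%. The mean of this list was 6.47 ± 1.65 log2 CPM in DR day 3 and 3.26 ± 2.16 in IR day 3 (two-sided exact permutation p = 0.0281, 0.112 after adjustment over the 4 tissue lists). It was 3.00 ± 1.62 in DR day 7 and 2.63 ± 0.318 in IR day 7 (exact permutation p = 0.937 for drying at day 7, 0.851 for time in IR and 0.00649, adjusted 0.026, for time in DR). The nasal gland list, which holds secreted proteins of nasal glands, took 11.05% ± 14.4 in IR day 3, 2.04% ± 2.05 in DR day 3, 1.97% ± 4.02 in IR day 7 and 2.38% ± 2.84 in DR day 7. Its highest shares were 31.7% and 26.7% in IR day 3 replicates 4 and 3. Its list mean gave exact permutation p-values of 0.753, 0.838, 0.271 and 0.156 for drying at day 3, drying at day 7, time in IR and time in DR. The olfactory epithelium list gave 0.805, 0.396, 0.175 and 0.273 in the same order, and the ciliated respiratory epithelium list 0.833, 0.121, 0.74 and 0.0368 (adjusted 0.0736). Ribosomal RNA took 18.0% ± 6.94 of counts in IR day 3, 20.6% ± 8.21 in DR day 3, 18.4% ± 4.74 in IR day 7 and 22.7% ± 7.24 in DR day 7, with exact permutation p-values of 0.591, 0.249, 0.92 and 0.626. These shares add Rn45s to Rn18s, Rn28s and Rn5-8s, entries that can count the same reads.

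**Figure D2:**
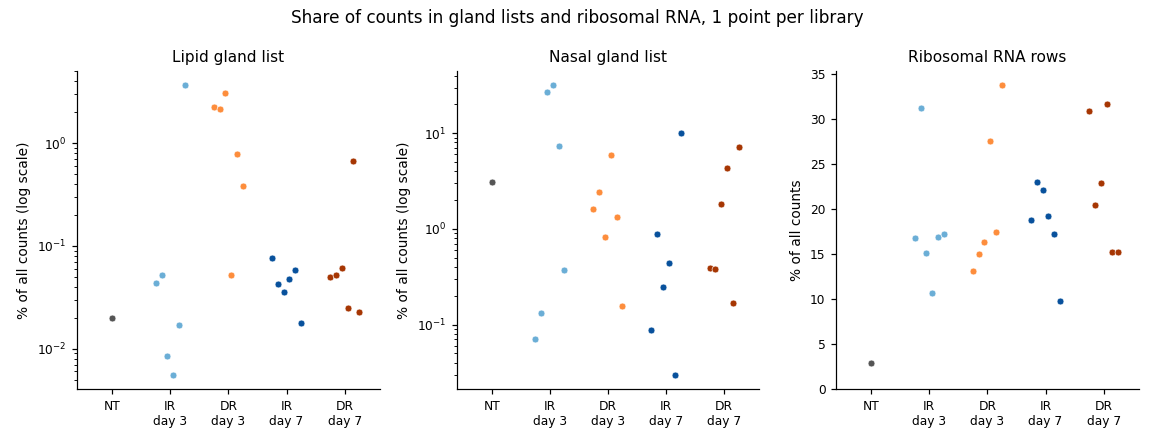
Share of all counts (%, y axis) in the lipid gland list and the nasal gland list (both on log axes) and in ribosomal RNA (linear axis), by group on the x axis, 1 point per library. The lipid gland share exceeds 2% in 4 libraries, IR day 3 replicate 6 and DR day 3 replicates 1 to 3, and the nasal gland share reaches 31.7% in IR day 3.

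The contrast DR vs IR day 3 asks how the longer dry period altered expression 3 days after replantation. Its 6 list calls were made by camera with the preset correlation, and 0 lists were called with an estimated correlation (adjusted p between 0.707 and 1 for the 6). Skeletal muscle genes were higher in DR, with all 14 measured members positive, a median log2 fold change of 2.66 and 5 members past the threshold when adjusted over the list alone. Pvalb, a calcium buffer of fast fibres, differed by 3.43 (SE 1.11, n = 6 per group), and Atp2a1, the calcium pump of their sarcoplasmic reticulum, by 2.51 (SE 0.87). Genes of oxidative phosphorylation, the respiratory chain of mitochondria, were positive in 27 of 28 members with a median of 0.215, for example Cox5a at 0.39 (SE 0.203) and Atp5b at 0.29 (SE 0.187). Genes of the Nrf2 response to oxidants were positive in 12 of 17 members with a median of 0.40, among them Gclc, which makes glutathione, at 0.58 (SE 0.348) and Srxn1 at 0.60 (SE 0.399).

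Lower in DR at day 3 were the T and NK cell list, with 11 of 13 members negative and a median of -0.58, and the list of the neutrophil and granulocyte precursor, with 11 of 15 negative and a median of -0.61. Lck and Zap70, kinases of T cell receptor signalling, differed by -1.09 (SE 0.425) and -1.85 (SE 0.834), and the granule proteins Ngp and Camp by -2.15 (SE 1.23) and -1.30 (SE 1.04). Cytosolic ribosome genes were negative in 24 of 28 members with a median of -0.105, such as Rpl8 at -0.20. No member of these 3 lists passed when adjusted over the list alone. Markers of resorption and matrix differed by less than their standard error, with Acp5 at -0.09 (SE 0.904), Ctsk at 0.28 (SE 0.942), Postn at -0.12 (SE 0.837) and Col1a1 at -0.30 (SE 0.652). So did Tnfrsf11b (0.25, SE 0.512), Il1b (0.25, SE 1.25), Il6 (0.10, SE 1.21), S100a8 (0.13, SE 0.972) and Mki67 (-0.49, SE 0.59). Bglap, which encodes osteocalcin, was at -0.96 (SE 0.61). Tnfsf11 and Dspp were too low to be tested.

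Of the 34 lists, camera placed 6 past the threshold in DR vs IR day 3. The adjusted p-values were 4.51e-11 for skeletal muscle (adjusted p = 0.792 with an estimated correlation), 2.03e-05 for oxidative phosphorylation, 0.000511 for the cytosolic ribosome, 0.0151 for the T and NK cell list and 0.0184 for the neutrophil list (adjusted p = 1 with an estimated correlation for these 4). The Nrf2 list had 0.0139 (adjusted p = 0.707 with an estimated correlation). Its mean per library was 6.53 ± 0.362 in DR and 5.93 ± 0.335 in IR (exact permutation p = 0.013, adjusted 0.442), while skeletal muscle stood at 6.74 ± 2.56 and 3.19 ± 2.87 (exact permutation p = 0.0519). In the same libraries the lipid gland share was 1.44% in DR and 0.63% in IR, and the nasal gland share 2.04% and 11.05%. With 3 tissue lists as covariates camera called 21 lists, 20 higher and 1 lower, and the adjusted p became 0.454 for the T and NK cell list, 0.641 for the cytosolic ribosome and 0.951 for the oxidative stress and Nrf2 list, and oxidative phosphorylation (3.76e-06, lower) and the neutrophil and granulocyte precursor list (0.00824, higher) turned direction. The neutrophil list was lost with the other scalings (0.0573 and 0.0865) and the T and NK cell list likewise (0.0512 and 0.0865). Without the 6 libraries of high gland share the adjusted p was 0.105 for the T and NK cell list, 0.789 for the cytosolic ribosome, 0.169 for the neutrophil and granulocyte precursor list and 0.169 for the oxidative stress and Nrf2 list. Median and mean of the list both opposed the sign of the camera test, without a call, for the osteoclast, cartilage, B cell, macrophage, cytokine and protease lists, and 1 of them did so for the Schwann cell, hypoxia and p53 lists.

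No single gene passed in DR vs IR day 3 by edgeR. The count was 0 higher and 0 lower, 313 genes had an unadjusted p under 0.05 against 575 expected by chance, and DESeq2 and limma-voom also called 0, whereas limma-voom with sample quality weights called 1190 (976 higher, 214 lower). Without IR day 3 replicate 6, the library with the highest lipid gland share, edgeR called 576 genes (526 higher, 50 lower), and with 3 tissue covariates 349 (164 higher, 185 lower). Among genes of smallest p, all with an adjusted p of 0.983, Lrrn4cl was at 2.18 (SE 0.502), Tmem220 at 1.04 (SE 0.24) and Ada, which degrades adenosine, at 2.37 (SE 0.705). Folr1, a folate receptor, was at 3.73 (SE 1.08) and Parp16 at -1.56 (SE 0.462), with Ogt at -0.47, Acap3 at -0.60 and Arfip2 at -0.59. Ogfod3 was at -2.30 (SE 0.679) and at -0.15 without IR day 3 replicate 4, and Ddit4l2 at 1.53 (SE 0.469) and at 0.99 without DR day 3 replicate 1.

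The contrast DR vs IR day 7 asks the same at the later day. Its 11 list calls were made by camera with the preset correlation, and 0 lists were called with an estimated correlation (adjusted p of 0.826 or 0.971 for the 11). Skeletal muscle genes were lower in DR, with 13 of 14 members negative, a median of -3.20 and 11 members past the threshold when adjusted over the list alone, for example the fast myosin Myh1 at -3.81 (SE 1.42, n = 6 per group) and Mylpf at -3.36 (SE 1.3). Lymphocyte lists were higher in DR. All 6 members of the B cell and plasma cell list were positive (median 0.52), with the plasma cell protein Mzb1 at 1.21 (SE 0.714) and the B cell antigen Ms4a1 at 1.19 (SE 0.894). In the T and NK cell list 10 of 13 members were positive (median 0.335), with Cd3e at 0.94 (SE 0.746) and Zap70 at 0.79 (SE 0.744). Cartilage genes were positive in 6 of 7 members (median 0.72), among them Col2a1 at 1.24 (SE 1.1) and Lect1 at 1.40 (SE 1.35).

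Osteoclast genes were negative in all 11 members at day 7 with a median of -0.42, such as Ostm1, needed for the acid-secreting membrane of the osteoclast, at -0.28 (SE 0.171) and Nfatc1 at -0.28 (SE 0.282). The odontoblast and dental pulp list was negative in 9 of 13 members (median -0.40), with the neuropeptide gene Tac1 at -1.67 (SE 0.87) and the tooth transcription factor Barx1 at -0.77 (SE 0.588). Its list mean was 2.82 ± 0.138 in DR and 3.20 ± 0.155 in IR (exact permutation p = 0.00216, the smallest possible, adjusted 0.0734). Endothelial genes were negative in 13 of 14 members (median -0.30), with Esam at -0.65 (SE 0.515) and Vwf at -0.53 (SE 0.463). Smaller negative medians belonged to the pericyte list (-0.19, 8 of 11 members), the hypoxia list (-0.17, 20 of 21), oxidative phosphorylation (-0.14, 26 of 28) and the cytosolic ribosome (-0.0855, 28 of 28). No member of any list other than skeletal muscle passed when adjusted over the list alone. Acp5 (-0.44, SE 0.906), Ctsk (-0.46, SE 0.943), Tnfrsf11b (0.37, SE 0.515), Postn (-0.23, SE 0.837), Col1a1 (-0.28, SE 0.652), Bglap (-0.09, SE 0.605), Il1b (-0.13, SE 1.25), Il6 (-0.87, SE 1.22), S100a8 (-0.57, SE 0.975) and Mki67 (0.26, SE 0.589) differed by less than their standard error. That error uses the spread shared by all 4 groups, and the day 3 libraries were more spread. For Acp5 the SD was 2.74 in IR and 2.62 in DR at day 3, but 0.5 and 0.287 at day 7. Small differences at day 7 can therefore be missed, and these values do not show that drying had no effect.

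Camera placed 11 of the 34 lists past the threshold in DR vs IR day 7, 3 higher and 8 lower. Its adjusted p-values were 2.81e-07 for skeletal muscle, 0.00929 for cartilage, 0.0187 for the odontoblast list, 0.0188 for the B cell list and 0.0443 for the pericyte list (adjusted p = 0.826 with an estimated correlation for each). They were 0.00142 for oxidative phosphorylation, 0.00155 for the ribosome, 0.0157 for the T and NK cell list, 0.0185 for endothelium, 0.0362 for hypoxia and 0.0443 for osteoclast (adjusted p = 0.971 with an estimated correlation for each). The skeletal muscle mean was 2.73 ± 1.31 in DR and 4.80 ± 2.45 in IR (exact permutation p = 0.0996), with IR libraries between 1.16 and 7.10. The lipid gland share was 0.147% in DR and 0.0464% in IR, and the nasal gland share 2.38% and 1.97%. With 3 tissue covariates the adjusted p was 0.97 for the cytosolic ribosome, 0.239 for endothelium, 0.938 for the hypoxia response, 0.451 for osteoclast and 0.198 for pericyte and smooth muscle. RLE scaling gave 0.0598 for osteoclast and for pericyte and smooth muscle. Median, mean or both opposed the sign of the camera test, without a call, for the osteocyte, mast cell, Schwann cell, osteoclastogenic, cytokine, interferon, cell cycle, p53 and heat shock lists.

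At day 7 the DR and IR libraries of the same replicate number deviated together, and a fit of these 12 libraries with the number as a block, added after the data had been seen, moved several lists in DR vs IR day 7. Camera then placed 18 lists past the threshold, 4 higher and 14 lower, while edgeR called 0 genes with 783 at an unadjusted p under 0.05. The odontoblast and dental pulp call was not made in it (adjusted p = 0.0713). Calls made only with the block were matrix proteases (5.28e-06), collagen (6.38e-05), macrophage (0.000245), neutrophil (0.0023), immediate early (0.00856), periodontal ligament (0.0115) and adipocyte genes (0.0235), all lower, and ameloblast genes (0.0235), higher. With an estimated correlation 0 lists were called with the block (adjusted p between 0.374 and 0.713 for the 18). The exact sign-flip test of paired list means placed 0 of the 34 lists past the threshold. For the lists called lower only with the block its adjusted p was 0.472 for collagen, 0.496 for proteases and for neutrophil, 0.664 for macrophage, 0.767 for immediate early, 0.924 for ligament and 0.963 for adipocyte genes, with 3 of 6 pairs lower for ligament and for adipocyte and 4 of 6 for the others. Between pairs, the B cell list was higher in DR by 0.705 ± 0.456, the T and NK cell list by 0.401 ± 0.451 and the ameloblast list by 0.599 ± 0.365, each in 6 of 6 pairs, and the odontoblast list differed by -0.38 ± 0.177 in 6 of 6. For these 4 lists the exact sign-flip p was 0.0312, the smallest that 6 pairs allow (adjusted 0.266), where 1.06 of 34 lists with 1 sign are expected by chance.

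With the spread shared with the day 3 libraries, no single gene passed in DR vs IR day 7 by edgeR. It called 0 genes with 206 at an unadjusted p under 0.05 against 575 expected by chance, limma-voom called 0 with and without sample quality weights, and DESeq2 called 3 higher (Aadacl3, Fabp2 and Hsd3b6, named after their values were seen). Among genes of smallest p, all with an adjusted p of 1, Ada was at -2.53 (SE 0.7), Hfe2, a muscle-expressed regulator of iron, at -3.11 (SE 1.04), Tspan9 at -0.63 (SE 0.22), Smurf1 at -0.68 (SE 0.235), Ubap1 at 0.47 (SE 0.167) and the Wnt receptor Lrp6 at 0.72 (SE 0.254). Crisp1 was at -7.44 (SE 1.95) and at -1.26 without IR day 7 replicate 5. The neighbouring genes Dnase1 and Trap1, whose reads cannot be told apart with certainty, were at -5.64 (SE 1.93) and -4.23 (SE 1.48), and at -2.47 and -1.25 without the same library. Spt1, a salivary protein gene, was at 5.24 (SE 1.87) and at -1.19 without DR day 7 replicate 6.

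**Figure D3:**
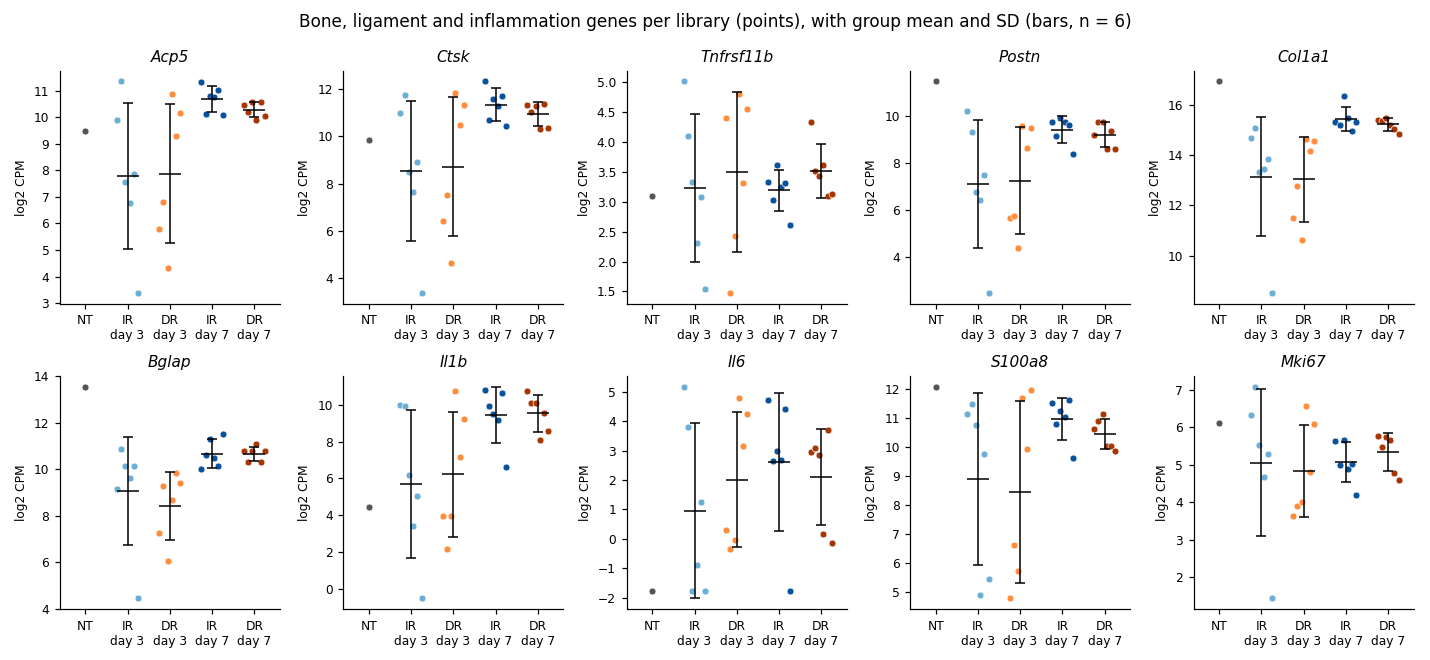
Log2 CPM (y axis) of 10 genes of resorption, matrix, inflammation and division by group (x axis), 1 point per library with the group mean and SD as bars (n = 6, NT a single point). Col1a1 spans 13.15 ± 2.38 in IR day 3 and 13.04 ± 1.7 in DR day 3, and lies at 15.45 ± 0.484 and 15.23 ± 0.246 at day 7.

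The contrast day 7 vs day 3 IR follows healing after the short dry period. Among called genes with an average log2 CPM of 3 or more, Ada rose most, by 4.28 on the log2 scale (SE 0.762, adjusted p = 0.0229, n = 6 per group), from 2.77 ± 1.01 to 6.56 ± 1.80 log2 CPM. Eln, which encodes elastin, rose by 2.08 (SE 0.386, adjusted p = 0.0318), from 4.43 ± 1.05 to 6.75 ± 0.351, and Fbln1, another protein of the extracellular matrix, by 1.34 (SE 0.274, adjusted p = 0.0441). Lrrn4cl rose by 2.50 (SE 0.505), Dennd1c by 1.93 (SE 0.367) and Arrdc2 by 1.26 (SE 0.227). Falls were seen for Slc35a3, a nucleotide-sugar transporter, by -1.93 (SE 0.378), for Ngly1, which strips glycans from misfolded proteins, by -1.80 (SE 0.315), for Eapp by -0.92 (SE 0.187) and for the fatty acid desaturase Scd2 by -0.74 (SE 0.146). Each of these calls was lost in 6 to 10 of the 12 fits that left out 1 library, with no change of sign.

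Immune lists were higher at day 7 in IR by camera with its preset correlation, and not past the threshold with an estimated correlation (adjusted p = 0.373 for each of the 5 below), by fry (0.0504 to 0.0873) or by list mean (0.0734 to 0.108). All 8 members of antigen presentation by MHC class II were positive and passed when adjusted over the list alone (median 1.20), with the protease Ctss at 1.58 (SE 0.431) and the class II transactivator Ciita at 1.74 (SE 0.478). The MHC class II mean went from 6.14 ± 1.23 to 7.65 ± 0.363 (exact permutation p = 0.00216, adjusted 0.0734). The macrophage list was positive in 16 of 16 members (median 1.41, 8 past when adjusted over the list alone), with Adgre1 at 2.27 (SE 0.548) and the complement gene C1qb at 1.40 (SE 0.382). Interferon-stimulated genes were positive in 17 of 17 members (median 1.33, 9 past over the list alone), such as Mx1 at 2.46 (SE 0.651) and Isg15 at 2.69 (SE 0.836). The T and NK cell list had 12 of 13 members positive (median 1.56, 4 past over the list alone), with Cd8a at 2.26 (SE 0.695) and Cd2 at 2.36 (SE 0.763). The cytokine list had 20 of 23 (median 1.46, 3 past over the list alone), with the chemokines Cxcl13 at 2.51 (SE 0.723) and Cxcl11 at 3.66 (SE 1.06). No member of these 5 lists passed when adjusted over all genes.

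Matrix and bone lists were also higher at day 7 in IR by camera, and likewise not with an estimated correlation (adjusted p = 0.373 for collagen, ligament, osteoblast and osteoclast). Collagen and matrix genes were positive in 20 of 24 members (median 0.935), of which Eln passed over all genes and over the list alone. Periodontal ligament genes were positive in 16 of 17 (median 0.79, 1 past over the list alone), with Col14a1 at 1.34 (SE 0.392) and Cilp at 1.63 (SE 0.618). Osteoblast genes were positive in 14 of 14 (median 0.53, 0 past), with Col1a2 at 1.65 (SE 0.578) and Phospho1, which starts mineral formation, at 0.93 (SE 0.387). Osteoclast genes were positive in 11 of 11 (median 0.63, 1 past over the list alone), with Ostm1 at 0.63 (SE 0.171) and the receptor gene Oscar at 1.76 (SE 0.911). Oxidative phosphorylation was negative in 26 of 28 members (median -0.28, 0 past), with Uqcrb at -0.65 (SE 0.241) and Ndufs1 at -0.84 (SE 0.333). The heat shock list was negative in 14 of 22 (median -0.32, 5 lower over the list alone), with the chaperones Hsph1 at -0.80 (SE 0.175) and Hspa5 at -0.67 (SE 0.155). Single markers did not pass, with Col1a1 at 1.53 (SE 0.666, adjusted p = 0.204), Bglap at 0.95 (SE 0.61, 0.373), Acp5 at 1.35 (SE 0.92, 0.401), Ctsk at 1.39 (SE 0.958, 0.404), Postn at 0.99 (SE 0.845, 0.498), Il1b at 1.46 (SE 1.27, 0.509), S100a8 at 0.75 (SE 0.977, 0.667), Il6 at 0.36 (SE 1.21, 0.881), Tnfrsf11b at -0.46 (SE 0.515, 0.618) and Mki67 at -0.63 (SE 0.591, 0.539).

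Camera placed 21 of 34 lists past the threshold in day 7 vs day 3 IR, 19 higher and 2 lower. The adjusted p was 5.05e-08 for macrophage and for collagen, 3.15e-07 for interferon, 1.01e-06 for matrix proteases, 2.43e-06 for MHC class II, 3.65e-06 for the ribosome, 6.58e-06 for the cytokine and ligament lists and 4.45e-05 for endothelium. It was 0.000118 for osteoblast, 0.00012 for the T and NK cell list, 0.000196 for immediate early genes, 0.000236 for osteoclast, 0.000839 for Wnt and BMP genes, 0.00111 for keratinocyte, 0.0088 for heat shock, 0.0123 for odontoblast and 0.044 for pericyte (adjusted p = 0.373 with an estimated correlation for each of these 18). The osteoclastogenic list had 0.0118, hypoxia 0.0119 and oxidative phosphorylation 0.00127 (adjusted p = 0.434, 0.51 and 0.535 with an estimated correlation). The nasal gland share was 11.05% at day 3 and 1.97% at day 7, and the lipid gland share 0.63% and 0.0464%. With 3 tissue covariates 12 lists were past the threshold, and without the 6 libraries of high gland share 15. In both fits the calls of osteoclast (0.112 and 0.0602), odontoblast and dental pulp (0.124 and 0.181) and oxidative phosphorylation (0.121 and 0.978) were lost, and osteoblast and bone matrix was lost in the second (0.0691). Medians were negative against a camera sign of higher, without a call, for the cartilage, neutrophil, erythroid and cell cycle lists.

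By edgeR 16 genes were called in day 7 vs day 3 IR, 12 higher and 4 lower, with 2340 at an unadjusted p under 0.05 against 575 expected by chance. DESeq2 called 748 (249 higher, 499 lower), limma-voom 9, and limma-voom with sample quality weights 4394 (2317 higher, 2077 lower), and upper-quartile scaling gave 12 higher and 8 lower. The count was 402 without IR day 3 replicate 1, 166 without replicate 2 and 28 without replicate 5. It was 0 without IR day 3 replicate 3, 4 or 6 or IR day 7 replicate 2 or 4, and 8, 5 and 3 without IR day 7 replicate 1, 3 and 5. Without the 6 libraries of high gland share 1 gene was called, Ngly1. With 3 tissue covariates 17 were called, 4 of them among the 16, with the lipid gland covariate 46 (23 higher, 23 lower) and with 6 covariates 0.

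**Figure D4:**
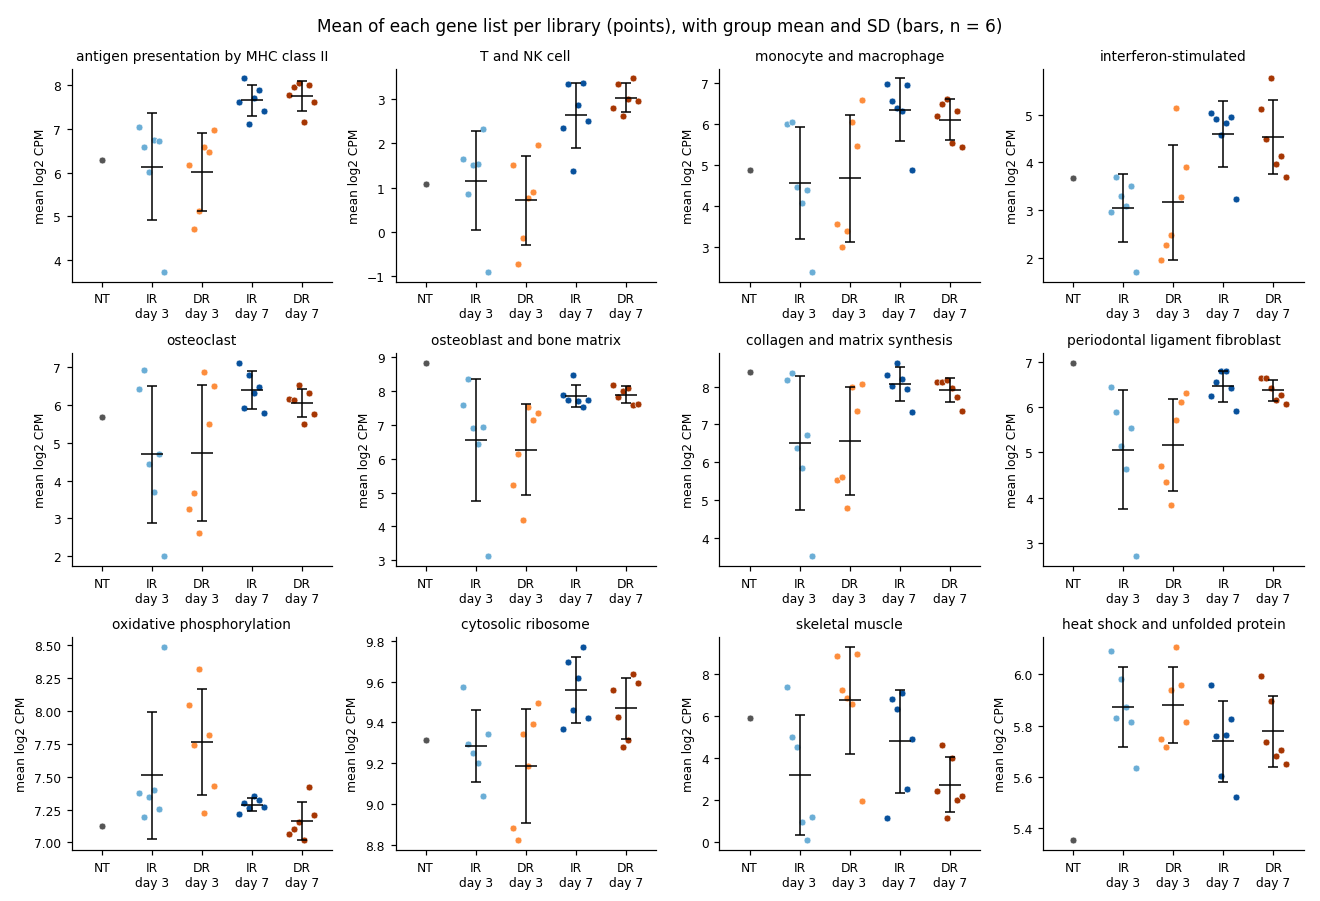
Mean log2 CPM (y axis) of the tested members of 12 gene lists by group (x axis), 1 point per library with the group mean and SD as bars (n = 6, NT a single point). MHC class II stands at 6.14 ± 1.23 and 6.01 ± 0.89 in IR and DR at day 3 and at 7.65 ± 0.363 and 7.76 ± 0.338 at day 7, while oxidative phosphorylation in DR goes from 7.76 ± 0.399 to 7.16 ± 0.143.

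The contrast day 7 vs day 3 DR follows healing after the long dry period. Lymphocyte and antigen presentation lists had mostly positive members, none past over all genes, and their camera calls below were lost with an estimated correlation (adjusted p = 0.395 for each). The T and NK cell list was positive in 12 of 13 members (median 2.26, 11 past when adjusted over the list alone), with Lck at 2.29 (SE 0.433) and Zap70 at 3.65 (SE 0.856). Its mean went from 0.72 ± 0.996 to 3.03 ± 0.32 (n = 6, exact permutation p = 0.00216, adjusted 0.0184). Antigen presentation by MHC class II was positive in all 8 members, each past over the list alone (median 1.58), with the invariant chain Cd74 at 1.88 (SE 0.432) and RT1-Db1 at 1.75 (SE 0.414). The mean over these members went from 6.01 ± 0.89 to 7.76 ± 0.338 (exact permutation p = 0.00216, adjusted 0.0184). The B cell and plasma cell list was positive in 5 of 6 members (median 2.58, 4 past over the list alone), with Cd79b at 2.94 (SE 0.803) and Mzb1 at 2.70 (SE 0.757). The B cell mean went from 2.66 ± 0.666 to 4.52 ± 0.727 (exact permutation p = 0.00433, adjusted 0.021).

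Genes of energy metabolism and muscle were lower at day 7 in DR by camera, and without a call at an estimated correlation (adjusted p = 0.395 for each list). All 28 members of oxidative phosphorylation were negative, 23 of them past when adjusted over the list alone (median -0.63), with cytochrome c (Cycs) at -0.70 (SE 0.169) and Ndufb3 at -1.02 (SE 0.257). The list mean went from 7.76 ± 0.399 to 7.16 ± 0.143 (exact permutation p = 0.00433, adjusted 0.021). All 14 skeletal muscle members were negative and past over the list alone (median -4.79), with Atp2a1 at -4.17 (SE 0.939) and Pvalb at -4.82 (SE 1.2). The muscle mean went from 6.74 ± 2.56 to 2.73 ± 1.31 (exact permutation p = 0.0152, adjusted 0.0646). The heat shock list was negative in 15 of 22 members (median -0.22, 4 lower and 1 higher over the list alone), with Hsph1 at -0.74 (SE 0.174) and Hspa8 at -0.62 (SE 0.149).

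Bone, ligament and epithelial lists were higher at day 7 in DR by camera, and without a call at an estimated correlation (adjusted p = 0.395 for each list). With 3 tissue covariates the osteoblast call was lost (0.117) and collagen turned lower. Osteoblast genes were positive in 14 of 14 members (median 1.15, 1 past over the list alone), with Smpd3 at 1.37 (SE 0.366) and Bglap at 1.82 (SE 0.624, adjusted p = 0.11). The osteoblast mean went from 6.27 ± 1.34 to 7.89 ± 0.25 (exact permutation p = 0.00216, adjusted 0.0184). The periodontal ligament list was positive in 15 of 17 (median 0.79, 1 past over the list alone), with the tendon and ligament gene Tnmd at 2.27 (SE 0.639) and Ogn at 0.79 (SE 0.262). Keratinocyte genes were positive in 12 of 15 (median 0.72, 0 past), with Krt10 at 2.95 (SE 0.957) and Krt1 at 2.63 (SE 0.952). Their list mean had an adjusted exact permutation p of 0.0184, as against 0.021 for Wnt and BMP genes (median 0.74) and 0.0654 for the ligament list. Collagen genes were positive in 24 of 24 (median 0.79, 1 past over the list alone), and the cytokine list in 19 of 23 (median 1.08, 2 past over the list alone). The macrophage list was positive in 15 of 16 (median 1.03), while Cd163, a scavenger receptor of tissue macrophages, lay at -1.78 (SE 0.497) and was the 1 member past over the list alone. Interferon-stimulated genes were positive in 17 of 17 (median 0.965, 0 past). Col1a1 was at 1.55 (SE 0.666, adjusted p = 0.174), Acp5 at 0.99 (SE 0.913, 0.536), Postn at 0.89 (SE 0.843, 0.552), Il1b at 1.08 (SE 1.26, 0.637), Ctsk at 0.64 (SE 0.945, 0.719), Tnfrsf11b at -0.34 (SE 0.513, 0.726), Il6 at -0.62 (SE 1.22, 0.8), Mki67 at 0.12 (SE 0.589, 0.928) and S100a8 at 0.05 (SE 0.972, 0.984).

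Camera placed 22 of 34 lists past the threshold in day 7 vs day 3 DR, 19 higher and 3 lower. The adjusted p was 1.73e-12 for oxidative phosphorylation, 2.11e-08 for the T and NK cell list, 6.04e-07 for MHC class II, 9.1e-07 for skeletal muscle and for collagen, 1.55e-06 for the cytokine and ribosome lists, 1.72e-06 for osteoblast, 3.89e-06 for interferon and 8.83e-06 for macrophage. It was 0.000155 for the ligament and Wnt and BMP lists, 0.000178 for immediate early, 0.00473 for osteoclastogenic, 0.00542 for keratinocyte, 0.0201 for the B cell and cartilage lists and 0.0291 for heat shock (adjusted p = 0.395 with an estimated correlation for each of these 18). Matrix proteases had 0.000155, osteoclast and endothelium 0.00465 each (adjusted p = 0.407 with an estimated correlation) and the neutrophil list 0.0486 (adjusted p = 0.541 with an estimated correlation), with a median of 0.0515 and a mean of -0.109 that differ in sign. Fry called 4 of the lists, T and NK cell (adjusted p = 0.00635), MHC class II (0.0121), heat shock (0.0126) and oxidative phosphorylation (0.0344). The lipid gland share was 1.44% in DR day 3 and 0.147% in DR day 7. The nasal gland share was 2.04% and 2.38%. With 3 tissue covariates 18 lists were past the threshold, and without the 6 libraries of high gland share 11. In the first fit only the B cell and plasma cell (1.17e-05), T and NK cell (7.54e-06) and cytosolic ribosome (0.00349) lists stayed higher. In that fit 10 lists turned to lower, osteoclast, cytokine, macrophage, osteoclastogenic, collagen, endothelium, immediate early, neutrophil, Wnt and BMP and proteases. Others were lost, among them antigen presentation by MHC class II (0.0847), osteoblast and bone matrix (0.117) and oxidative phosphorylation (0.485). Without the 6 libraries of high gland share the calls of monocyte and macrophage (0.362), collagen and matrix synthesis (0.0654), periodontal ligament fibroblast (0.362) and osteoclast (0.407) were among the 12 lost. The neutrophil and granulocyte precursor list was lost with the other scalings (0.0556 and 0.0944).

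Rfx5, a regulator of MHC class II genes, was the 1 gene called by edgeR in day 7 vs day 3 DR, higher by 1.11 (SE 0.182, adjusted p = 0.0378). In this contrast 2589 genes had an unadjusted p under 0.05 against 575 expected by chance. DESeq2 called 1064 (346 higher, 718 lower), limma-voom 1, limma-voom with sample quality weights 3305 (1603 higher, 1702 lower), the 2 compared groups alone 43 (27 higher, 16 lower) and upper-quartile scaling 20 (16 higher, 4 lower). With 3 tissue covariates 208 were called (135 higher, 73 lower), Rfx5 among them, and 0 with the lipid gland covariate, with 6 covariates or without the 6 libraries of high gland share. Leaving out DR day 3 replicate 4 gave 369 genes, replicate 6 76 and replicate 5 6, and leaving out any other library except DR day 7 replicate 4 gave 0. After Rfx5 the smallest adjusted p was 0.059, shared by Lck (2.29), Arrdc2 (1.14, SE 0.225), Cd72, a B cell receptor, (0.85, SE 0.169), Tesk1 (0.76, SE 0.155), Atp5a1 of the ATP synthase (-0.84, SE 0.16), Timm21 (-1.17, SE 0.23), Ugp2 (-0.84, SE 0.17), Pgm1 of glycogen metabolism (-1.38, SE 0.282) and Zdhhc4 (-0.83, SE 0.172).

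The interaction of drying and day tests whether the difference between DR and IR changed from day 3 to day 7. Skeletal muscle genes went from higher in DR at day 3 to lower at day 7, with all 14 members negative in the interaction, a median of -5.36 and 13 past when adjusted over the list alone (camera adjusted p = 1.03e-16, adjusted p = 0.577 with an estimated correlation). Atp2a1 was at -4.73 (SE 1.23, n = 6 per group) and the fast troponin Tnnt3 at -5.11 (SE 1.42). Oxidative phosphorylation was negative in 27 of 28 members (median -0.35, camera adjusted p = 1.32e-08), with Cox6c at -0.48 (SE 0.238) and Cox5a at -0.58 (SE 0.286). The T and NK cell list was positive in 11 of 13 (median 0.90, camera adjusted p = 0.00105), with Lck at 1.43 (SE 0.588) and Zap70 at 2.64 (SE 1.12). The pericyte and smooth muscle list was negative in 10 of 11 (median -0.34, 1 past over the list alone, camera adjusted p = 0.0151), with the intermediate filament gene Des, which striated muscle also expresses, at -3.38 (SE 1.04) and Kcnj8 at -2.30 (SE 1.13). These last 3 lists had an adjusted p = 0.654 with an estimated correlation, and fry called 0 of 34. Cox6c and Cox5a turned positive with 6 tissue covariates, 1 of them the skeletal muscle list.

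No gene passed in the interaction of drying and day by edgeR (0 called, smallest adjusted p 0.689), with 346 at an unadjusted p under 0.05 against 575 expected by chance. Limma-voom called 0, DESeq2 11 (3 higher, 8 lower) and limma-voom with sample quality weights 522 (115 higher, 407 lower). Ada led with -4.89 (SE 0.994, adjusted p = 0.689), its level being 2.77 and 6.56 log2 CPM at days 3 and 7 in IR and 4.78 and 4.59 in DR. Several of the next genes, all with an adjusted p of 1, belong to muscle, namely Sh3bgr at -4.54 (SE 1.21), Trdn, which anchors calcium release in the fibre, at -4.87 (SE 1.33), Hfe2 at -5.38 (SE 1.42) and Hspb6 at -2.85 (SE 0.835). Lrrn4cl was at -2.97 (SE 0.687), Rabep2 at -3.97 (SE 1.02) and Tmem220 at -1.21 (SE 0.336). None of the genes of resorption, matrix and inflammation passed (adjusted p = 1 for each), with Col1a1 at 0.02, Acp5 at -0.35, Ctsk at -0.75, Tnfrsf11b at 0.12, Postn at -0.11, Il1b at -0.38, Il6 at -0.97, S100a8 at -0.70, Mki67 at 0.75 and Bglap at 0.87 (SE 0.857). By list, camera called 20 with 3 tissue covariates (2 higher, 18 lower) against 4 without them, 3 of these 4 being among the 20 and oxidative phosphorylation lost (0.0697). Without the 6 libraries of high gland share it called 7 (2 higher, 5 lower), with the pericyte and smooth muscle call lost (0.185). Across genes, which are not independent replicates, the drying effects at both days had a Pearson r of -0.0567 (covariance -0.0138), inside the -0.47 to 0.422 of 100 shuffles. The day effects in IR and DR had an r of 0.67 (covariance 0.539), above the highest of 100 shuffled values (0.637) when libraries were shuffled singly. With same-numbered libraries kept together, 13 of 462 splits were as high, the highest other at 0.798, and with different numbers for IR and DR at day 7 r lay between 0.424 and 0.707.

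The single NT library, which has no replicate, held more transcripts of several tooth and blood-forming genes than the replanted libraries. Since its animal can differ from them in age, these ratios do not separate replantation from growth. Dspp, the main non-collagen protein gene of dentin, stood at 1070 CPM in NT and 2.92 CPM over the replanted libraries (log2 ratio -7.08). Genes of granulocyte precursors were lower in the replanted libraries than in NT, with Ngp at 552 against 13.3 CPM, Camp at 724 against 35.5, Mpo at -4.01 on the log2 scale and the defensin RatNP-3b at -3.81 (4240 against 298 CPM). Erythroid genes were lower too, with Ahsp at 716 against 19.1 CPM, Slc4a1 at -4.50 and Car1 at -3.98. Bglap had 12100 CPM in NT and between 478 and 1780 in the group means, Col1a1 126000 and between 13200 and 47300, Postn 2800 and between 329 and 725. Il1b went the other way, at 21.8 CPM in NT and between 349 and 992 in the groups. Il6 had 0 counts in NT, which allows up to 0.354 CPM at 3 counts for counting error alone, and 6.11 to 11.5 CPM in the groups. Acp5 had 706 CPM in NT and 664, 629, 1750 and 1250 in IR day 3, DR day 3, IR day 7 and DR day 7, and Ctsk 904 against 1060, 1300, 2870 and 2020. S100a8 had 4300 CPM in NT against 1250, 1390, 2190 and 1420, Mki67 68 against 53, 38.1, 35.3 and 40.7, and Tnfrsf11b 8.26 against 12.1, 14.6, 9.12 and 11.4.

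By list, the replanted libraries lay below NT for erythroid (median log2 ratio -3.05), neutrophil (-2.51), odontoblast (-1.39), osteoblast (-1.29), ligament (-0.88), collagen (-0.86), cell cycle (-0.72) and Wnt and BMP genes (-0.67), each at or under percentile 0.06 of 10000 random lists. They lay above NT in all 4 groups for cytokine (3.00) and Nrf2 genes (1.26), both at percentile 100, and for MHC class II (1.01, percentile 98.2), matrix protease (0.70, 98.3), osteoclast (0.88, 98.8) and hypoxia genes (0.47, 97.9). Osteoclast genes stood at 0.0167 and 0.0797 in IR and DR at day 3 and at 1.39 and 1.08 at day 7, and MHC class II at 0.196 and 0.19, then 1.51 and 1.44. Interferon genes (0.59, percentile 99.4) were below NT at day 3 (-0.37 in IR and -0.0772 in DR) and above it at day 7 (1.13 and 1.20). Macrophage genes (0.78, percentile 99.6) were at -0.13 and 0.16 at day 3 and at 1.34 and 1.05 at day 7. Skeletal muscle (0.59, percentile 98.6) ranged from 1.98 in DR day 3 to -2.29 in DR day 7, and the salivary list from 4.77 in IR day 7 to 0.0949 in DR day 3. The salivary median over all replanted libraries, 5.31, lay above that of each group (0.543 in IR day 3 and 0.639 in DR day 7) and so describes none of them. Of 6057 genes at 20 CPM or more, 1204 had 1 sign in all 24 replanted libraries, 379 higher and 825 lower. Among the highest ratios were Acsm1 at 5.39 (6.71 in DR day 3 and 1.27 in IR day 7), Amacr at 4.12 (5.40 and 0.56) and the ribosomal RNA Rn28s at 4.05. Acsm1 and Amacr are also among the leading genes of the first 2 principal components, and DR day 3, where they were highest, had the highest lipid gland share. Dhrs7 at 3.54 (4.56 and 0.817), Agps of ether lipid synthesis at 3.15 (4.25 and 0.96) and Alas1 of haem synthesis at 2.88 (3.89 and 1.27) were likewise highest in DR day 3 and lowest in IR day 7. G0s2, an inhibitor of fat breakdown, was at 4.08 (5.08 and 3.36) and LOC257642 at 3.38 (3.60 and 2.74). Scaling by library total in place of TMM gave 898 such genes (251 higher, 647 lower), of which 823 were among the 1204.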

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

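The search for single far-off libraries, the tissue lists, the tests on longer drying, on the weight of 1 library and on tissue covariates, the splits of DR against IR at day 3 and the splits and the sign-flip test of pairs at day 7 were chosen only after the results were seen.

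A single library lay far from the other 5 of its group in 9 of 64 groups of values searched, where chance gives about 5 percent. In IR day 3, replicate 6 held 3.65% of its counts in the lipid gland list against 0.0056% to 0.052% in the others, with Col1a1 at 8.51 log2 CPM against 13.3 to 15.1 and Bglap at 4.45 against 9.14 to 10.9. IR day 3 replicate 2 held 31.3% ribosomal RNA (15.6% in Rn45s alone) against 10.7% to 17.3%. In IR day 7, replicate 6 held 10.2% in the nasal gland list against 0.03% to 0.884% and 0.323% in the olfactory list against 0.0067% to 0.0649%, with Il6 at -1.78 log2 CPM against 2.64 to 4.74, and replicate 3 had Col1a1 at 16.4 against 15 to 15.5. DR day 7 replicate 5 held 0.668% in the lipid gland list against 0.0229% to 0.0612%.

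The drying difference changed between the days, by camera on the interaction, for the skeletal muscle (adjusted p = 1.03e-16), oxidative phosphorylation (1.32e-08), T and NK cell (0.00105) and pericyte (0.0151) lists. With an estimated correlation the adjusted p was 0.577 for skeletal muscle and 0.654 for the others.

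Other splits of the same libraries, 100 per contrast with the real one included, were used to see whether chance can be excluded. For genes called by edgeR in day 7 vs day 3 DR, 2 of 100 splits gave as many as the real 1, and the highest other gave 671. The real count is a single gene, Rfx5, whose call was lost in 8 of 12 fits without 1 library and in 7 of 14 other settings. Little rests on it, and chance is not excluded by this share. Nor can it be excluded for day 7 vs day 3 IR (real 16, 6 splits as large, highest other 1355). With a real count of 0 each of the 100 splits is as large by construction, so the splits decide nothing for DR vs IR day 3 (highest other 2271), DR vs IR day 7 (highest other 0) or the interaction (highest other 1). For lists past camera it cannot be excluded in any contrast, with real counts of 6, 11, 21, 22 and 4 for DR vs IR day 3, DR vs IR day 7, time in IR, time in DR and the interaction, 90, 25, 20, 8 and 89 splits as large, and highest others of 25, 19, 26, 24 and 23. With sample quality weights few splits were as large for time in IR (real 4394, 3 splits, highest other 4614) and time in DR (real 3305, 1 split, highest other 3286). Chance is less likely there, but these shares are not adjusted over the counts examined and do not exclude it. It cannot be excluded either, with weights, for DR vs IR day 3 (real 1190, 10 splits, highest other 3433) and the interaction (real 522, 10 splits, highest other 2817). For DR vs IR day 7 the real count of 0 (100 splits as large, highest other 16) again decides nothing. At day 7, where the numbers pair the libraries, 32 splits part each of the 6 pairs as the real one does. With the number as a block the real split placed 18 lists past camera. Only 1 split was as large, the real one, with a highest other of 17 and a median other of 11. The margin is 1 list, and 1 of 32 is the smallest share these splits allow. The pairing was itself found in these libraries. The exact sign-flip test of the same pairs placed 0 of 34 lists past the threshold (smallest adjusted p 0.266). Chance is therefore not excluded for the lists. With the block the edgeR count of 0 decides nothing (32 splits as large, highest other 1). Without a block chance cannot be excluded for the lists (real 11, 2 splits as large, highest other 11). The other splits exchange DR and IR within 1 or more pairs. Splits that call many times the real number point to a structure among the libraries that the groups do not hold.

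The first pattern weighed is the high lipid gland signal in DR day 3 libraries and in IR day 3 replicate 6, led by Thrsp, Sdr16c6 and Elovl3 (average 11.61, 8.53 and 8.55 log2 CPM). If gland tissue had entered the samples, the 6 other tested list members should follow the leading 6, but their median Spearman correlation was 0.202, between Cidea at 0.79 and Soat1 at -0.483, and members going both ways leave this open. Exchanged labels of IR day 3 replicate 6 and DR day 3 replicate 4 would give a correlation across genes between the drying effects at day 3 and day 7 of 0.0767 in place of -0.0567, inside the shuffled values that reach 0.422, so an exchange cannot be told apart from none. Longer drying stays open and cannot be told apart either, since the higher list mean in DR at day 3 (exact permutation p = 0.0281) was measured on a list written after its genes had shown the pattern, and at day 7 the difference was 0.374 (exact permutation p = 0.937).

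The second pattern is the 1190 genes called between DR and IR at day 3 with sample quality weights, where edgeR called 0. The low weight of IR day 3 replicate 6 (0.147, the lowest of 24) is needed for it, since 0 genes were called with that weight set to 1 and all others kept, against 655 to 1434 when the same was done for each other library. Gland tissue in the samples may also contribute, since 37 genes remained called with weights and the lipid gland list as a covariate. The lipid gland mean was 6.47 ± 1.65 log2 CPM in DR and 3.26 ± 2.16 in IR at day 3 (n = 6, exact permutation p adjusted over the 4 tissue lists 0.112), so the covariate overlaps with the groups and whether it removes gland tissue or an effect of drying stays open.

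The third pattern is the many resident and immune lists that were higher at day 7. Dilution at day 3 by tissue from glands and nose is a candidate explanation, since of 19 lists called higher 3 in DR and 8 in IR were still called higher with 3 tissue covariates (10 in DR turned lower, 0 in IR), and 7 and 12 without the 6 libraries of high gland share. The lipid gland covariate itself fell between the days in DR (exact permutation p = 0.00649), so part of a day effect is removed with it. Dilution by tissue without these genes leaves the T and NK cell mean minus that of 4 resident lists unchanged or higher at day 3. The prior count limits the fall of low values (T and NK cell mean 0.72 in DR, 1.16 in IR). In DR this difference went from -4.35 ± 1.03 to -3.24 ± 0.415 (n = 6, exact permutation p = 0.0411, unadjusted). In IR it went from -3.92 ± 1.08 to -3.79 ± 0.965 (exact permutation p = 0.807). The DR value speaks against such dilution alone there, for the T and NK cell list. The IR value decides nothing. Whether the other tissue also held resident genes was not tested, so dilution cannot be excluded in either group. A response to healing over time stays open and untested for all these lists.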

How the results depend on the processing

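The fit with pairs at day 7, the fits with tissue covariates, without the 6 libraries of high gland share and without ribosomal RNA genes, the exact test of list means, camera with an estimated correlation in the fits with pairs, with 3 covariates and without the 6 libraries, and camera after other scalings were chosen only after the result was seen. As fitted by edgeR, 0 genes were called in DR vs IR day 3 and DR vs IR day 7, 16 in day 7 vs day 3 IR, 1 in day 7 vs day 3 DR and 0 in the interaction of drying and day, and camera called 6, 11, 21, 22 and 4 lists. Values that turned direction are printed below as log2 fold changes, and none of them had passed in the main test; for each of them and for each count that moved, the cause was not tested.

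Sample quality weights called 1190 genes in DR vs IR day 3, 4394 in day 7 vs day 3 IR, 3305 in day 7 vs day 3 DR and 522 in the interaction of drying and day. Acp5 turned to 0.15, Postn 0.11 and S100a8 -0.74 in DR vs IR day 3. Bglap turned to 0.05178 and Spt1 -0.9991 in DR vs IR day 7. Tnfrsf11b turned to 0.16 in day 7 vs day 3 IR. Il6 turned to 1.005 and Tnfrsf11b 0.28 in day 7 vs day 3 DR. S100a8 turned to 0.13 in the interaction of drying and day. DESeq2 called 3 genes in DR vs IR day 7, 748 in day 7 vs day 3 IR, 1064 in day 7 vs day 3 DR and 11 in the interaction of drying and day. Plain limma-voom called 9 genes in day 7 vs day 3 IR. Acp5 turned to 0.05175, Postn 0.10 and S100a8 -0.49 in DR vs IR day 3. Bglap turned to 0.0002489, Il1b 0.08282 and Il6 0.11 in DR vs IR day 7. Il6 turned to 0.27 and Tnfrsf11b 0.03653 in day 7 vs day 3 DR. Col1a1 turned to -0.13 in the interaction of drying and day. An adjusted p limit of 0.01 called 0 genes in day 7 vs day 3 IR and 0 in day 7 vs day 3 DR. The stricter filter called 32 genes in day 7 vs day 3 IR.

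The fit without a filter called 0 genes in day 7 vs day 3 DR. Col1a1 turned to -0.0473 in the interaction of drying and day. RLE scaling called 0 genes in day 7 vs day 3 DR. Upper-quartile scaling called 20 genes in day 7 vs day 3 DR, 16 higher and 4 lower. The fit of only the 2 groups compared called 0 genes in day 7 vs day 3 IR and 43 in day 7 vs day 3 DR. The fit without ribosomal RNA genes called 0 genes in day 7 vs day 3 DR. Col1a1 turned to -0.04173 in the interaction of drying and day.

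The lipid gland covariate called 46 genes in day 7 vs day 3 IR and 0 in day 7 vs day 3 DR. Acp5 turned to 1.11, Atp5b -0.22, Bglap 0.60, Camp 1.23, Col1a1 1.31, Cox5a -0.03958, Gclc -0.005667, Mki67 1.07, Ngp 1.60, Postn 1.42 and Srxn1 -0.008659 in DR vs IR day 3. Acp5 turned to 0.02943, Bglap 0.16, Col1a1 0.11, Ctsk 0.04989, Il1b 0.57 and Postn 0.23 in DR vs IR day 7. Ctsk turned to -0.13, Mki67 -1.24, Postn -0.15 and S100a8 -1.28 in day 7 vs day 3 DR. Bglap turned to -0.44, Col1a1 -1.20, Mki67 -0.55 and Tnfrsf11b -0.86 in the interaction of drying and day.

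The fit with 3 tissue covariates called 349 genes in DR vs IR day 3 and 208 in day 7 vs day 3 DR, and 21 lists in DR vs IR day 3, 12 in day 7 vs day 3 IR and 20 in the interaction of drying and day. Acp5 turned to 2.26, Atp5b -0.19, Bglap 0.24, Camp 0.93, Col1a1 1.55, Mki67 1.45, Ngp 0.71 and Postn 2.38 in DR vs IR day 3. Acp5 turned to 0.335, Col1a1 0.15, Ctsk 0.45, Il1b 1.79, Il6 0.79, Postn 0.51 and S100a8 0.33 in DR vs IR day 7. Il6 turned to -1.05 and S100a8 -0.17 in day 7 vs day 3 IR. Acp5 turned to -0.84, Col1a1 -0.0808, Ctsk -1.25, Il1b -1.92, Mki67 -1.90, Postn -1.18 and S100a8 -2.12 in day 7 vs day 3 DR. Bglap turned to -0.31, Col1a1 -1.40, Mki67 -0.75 and Tnfrsf11b -1.12 in the interaction of drying and day.

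The fit with 6 tissue covariates called 0 genes in day 7 vs day 3 IR and 0 in day 7 vs day 3 DR. Acp5 turned to 2.23, Atp5b -0.25, Camp 0.725, Col1a1 1.335, Cox5a -0.17, Ddit4l2 -0.20, Folr1 -0.82, Mki67 1.41, Ngp 0.53, Ogfod3 0.33 and Postn 2.04 in DR vs IR day 3. Acp5 turned to 0.18, Cd3e -0.12, Col2a1 -0.82, Ctsk 0.20, Il1b 1.57, Lect1 -0.11, Ms4a1 -0.01695, Postn 0.0862 and S100a8 0.17 in DR vs IR day 7. Il1b turned to -0.10, Il6 -1.94, Postn -0.00912 and S100a8 -0.97 in day 7 vs day 3 IR. Acp5 turned to -1.12, Cd74 -0.32, Col1a1 -0.77, Ctsk -1.72, Il1b -2.425, Mki67 -1.99, Ndufb3 0.48, Ogn -0.03951, Pgm1 0.08938, Postn -1.97, RT1-Db1 -0.0641 and S100a8 -2.41 in day 7 vs day 3 DR. Bglap turned to -0.37, Col1a1 -1.57, Cox5a 0.19, Cox6c 0.06358, Hspb6 0.68, Mki67 -0.77, Sh3bgr 0.45 and Tnfrsf11b -0.99 in the interaction of drying and day.

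The fit without the 6 libraries of high gland share called 1 gene in day 7 vs day 3 IR and 0 in day 7 vs day 3 DR, and 11 lists in day 7 vs day 3 DR and 7 in the interaction of drying and day. Ogfod3 turned to 0.32 in DR vs IR day 3. Il6 turned to -0.59 in day 7 vs day 3 IR. Ctsk turned to -0.28, Mki67 -0.56 and S100a8 -0.89 in day 7 vs day 3 DR. Col1a1 turned to -0.12 in the interaction of drying and day.

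Camera with an estimated correlation called 0 lists in each of the 5 contrasts. The fry test called 0 lists in DR vs IR day 3, 0 in DR vs IR day 7, 0 in day 7 vs day 3 IR, 4 in day 7 vs day 3 DR and 0 in the interaction of drying and day. The exact permutation test of list means called 0 lists in DR vs IR day 3, 0 in DR vs IR day 7, 0 in day 7 vs day 3 IR and 7 in day 7 vs day 3 DR. Camera with an estimated correlation also called 0 lists in each contrast with 3 tissue covariates and without the 6 libraries of high gland share, and 0 in DR vs IR day 7 with the replicate block in the day 7 libraries only.

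The replicate number as a block was fitted over all 24 libraries and over the day 7 libraries alone. Only DR and IR at day 7 met the rule for pairs. In the other comparisons 1 of 6 pairs of the same number correlated over 0.1 for IR day 3 with DR day 3, 1 for IR day 3 with IR day 7, 3 for IR day 3 with DR day 7 and 0 for DR day 3 with either day 7 group, and by the deposited numbers 4 of 5 for IR day 3 with IR day 7, 3 with DR day 7, and 2 and 1 for DR day 3. The block over all libraries thus joins numbers across days without such a pairing. With the replicate block over all libraries, edgeR called 0 genes in day 7 vs day 3 IR and 0 in day 7 vs day 3 DR, and camera called 5, 13, 22, 20 and 4 lists. Acp5 turned to 0.33 and Postn 0.36 in DR vs IR day 3. Mki67 turned to -0.01642 and S100a8 -0.0475 in day 7 vs day 3 DR. Col1a1 turned to -0.07496 and Tnfrsf11b -0.0911 in the interaction of drying and day. With the block in the day 7 libraries camera called 18 lists in DR vs IR day 7 against 11 without it, and it changed no call other than those printed with it. Bglap turned to 0.01195 and Il1b 0.07159 in DR vs IR day 7.

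With 1 library left out in turn, counts of called genes ranged from 0 (without DR day 3 replicate 1) to 576 (without IR day 3 replicate 6) in DR vs IR day 3, 0 (without IR day 3 replicate 3) to 402 (without IR day 3 replicate 1) in day 7 vs day 3 IR and 0 (without DR day 3 replicate 1) to 369 (without DR day 3 replicate 4) in day 7 vs day 3 DR. Across these fits Acp5 lay between -0.79 and 1.12, Col1a1 -0.59 and 0.07261, Ctsk -0.33 and 1.095, Il1b -1.16 and 0.95, Il6 -0.59 and 1.53, Mki67 -0.98 and 0.01402, Postn -0.55 and 0.73, S100a8 -0.54 and 0.54 and Tnfrsf11b -0.01454 and 0.81 in DR vs IR day 3. Bglap lay between -0.20 and 0.14, Il1b -0.42 and 0.16 and Spt1 -1.19 and 5.87 in DR vs IR day 7. Il6 lay between -0.0771 and 1.78 and Tnfrsf11b -0.67 and 0.10 in day 7 vs day 3 IR. Il6 lay between -0.94 and 0.07415, Mki67 -0.06819 and 0.61 and S100a8 -0.21 and 0.72 in day 7 vs day 3 DR. Acp5 lay between -1.56 and 0.35, Col1a1 -0.35 and 0.31, Il1b -1.07 and 1.03, Postn -0.96 and 0.32 and Tnfrsf11b -0.44 and 0.38 in the interaction of drying and day. Of 2340 values of named genes in these fits 70 turned direction, 87 were no longer called and 60 were newly called.

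In simulated counts with genes independent of each other and equal spread at both days, edgeR found 65.3% of changes of 4-fold and 14% of changes of 2-fold in DR vs IR day 3, so smaller changes were mostly missed there. For DR vs IR day 7 these were 64% and 36.7%, for day 7 vs day 3 IR 62.5% and 34.7%, for day 7 vs day 3 DR 63.3% and 18%, and for the interaction of drying and day 50% and 8%.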

Other observations

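The exact permutation tests of list means, camera with an estimated correlation in the altered fits, the fits with tissue covariates and the fit without the 6 libraries of high gland share were chosen only after the result was seen, and the lists themselves were fixed before the data were examined.

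Genes of dividing cells gave no call in the contrasts as first fitted. The cell cycle list had 5 of 28 members positive in DR against IR at day 3 (median -0.20, camera adjusted p = 0.328) and 13 of 28 at day 7 (median -0.00514, 0.979), and its mean was 3.69 ± 1.13 log2 CPM in IR day 3, 3.68 ± 0.947 in DR day 3, 3.97 ± 0.222 in IR day 7 and 3.98 ± 0.261 in DR day 7 (SD, n = 6). Over time 9 of 28 members were positive in IR (median -0.10, 0.675) and 21 in DR (median 0.0639, 0.185). Without the 6 libraries of high gland share the cell cycle list was lower at day 7 in both, with adjusted p-values of 6.83e-07 in IR and 3.62e-06 in DR, and with 3 tissue covariates likewise (2.58e-08 and 1.28e-15), but with an estimated correlation it was not called (adjusted p = 0.59 and 0.542 without these libraries, 0.539 and 0.13 with the covariates). The first of these fits leaves 3 libraries in each day 3 group.

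Blood vessel genes were positive over time in 13 of 14 members in IR (median 0.73) and 13 of 14 in DR (median 0.46), and the endothelium mean went from 4.03 ± 0.928 to 5.00 ± 0.40 in IR (exact permutation p = 0.0433, adjusted 0.108) and from 4.13 ± 0.778 to 4.75 ± 0.234 in DR (exact permutation p = 0.121). Osteocyte genes, of the cells embedded in bone, were positive in 5 of 6 members over time in DR (median 0.74, camera adjusted p = 0.0865), with a mean of 4.86 ± 0.957 at day 3 and 5.92 ± 0.31 at day 7 (exact permutation p = 0.0195, adjusted 0.0663), and in 4 of 6 in IR (median 0.30, camera adjusted p = 0.129). Genes of p53 and apoptosis were positive in 13 of 17 members in DR (median 0.30, camera adjusted p = 0.0752) and 12 of 17 in IR (median 0.21, 0.145). Nerve and Schwann cell genes were negative in 9 of 11 members over time in DR (median -0.43, camera adjusted p = 0.626) and 6 of 11 in IR (median -0.50, 0.86). Enamel organ genes were negative in 4 of 5 members over time in IR (median -1.39, 0.601) and positive in 3 of 5 in DR (median 0.25, 0.588). Mast cell genes were positive in 8 of 10 members in DR (median 0.50, 0.0752) and 7 of 10 in IR (median 0.44, 0.145). The adipocyte list had 4 of 4 members positive in IR (median 0.77, 0.0734), 1 of them past when adjusted over the list alone, and 2 of 4 in DR (median -0.0482, 0.569). Erythroid means lay between 5.67 ± 1.17 in DR day 3 and 6.27 ± 1.01 in IR day 7, with exact permutation p-values of 0.848, 0.844, 0.641 and 0.45 for drying at day 3, drying at day 7, time in IR and time in DR.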
